A study of Homo sapiens with 7 samples.

How the data were processed

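Islet cells from 2 nondiabetic donors, called A and B here, were profiled in 7 droplet libraries with the 10x Genomics 3' protocol and polyadenylated RNA, per the labels. In 5 libraries (the pool libraries) the islets had received a pool of adenoviruses, each encoding 1 of 15 genes, called factors here, with its barcode. The other 2 libraries were controls whose virus label is NA. The labels name unsorted islet cells (islet) or beta cells enriched by FAD+ (FADplus) as the source. Per the submitters' processing notes the reads were handled with Cell Ranger 2.1.1 and STAR 2.5.2a against hg38. The authors deposited, for each library, a table of UMI counts per gene and cell and a table of barcode counts per cell, both whole numbers that were not normalized. The barcode tables held a row for each of the 15 factors, a row for the fluorescent protein BFP, whose role the labels do not state, and 32 rows named for guides. The deposited cells were taken as called by the authors, whose threshold for a cell is not stated.

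The library that the labels call a technical duplicate shared 6 cell barcodes with the library it duplicates, so the pair was read as 2 lanes of 1 sample and their sums were added, which left 6 analysis units (4 pool, 2 control). Cells with at least 500 genes and at most 20% mitochondrial counts were kept. Scrublet, run per library in scanpy 1.11.5, marked between 0 and 21 cells of a library. That share is too low for the caller to have worked, so doublets remain in the data and cells with several barcode calls or many UMIs can include them. Cells of all libraries were clustered together on 2000 variable genes without the 15 factors, with 30 principal components, 20 neighbours and the Leiden method at resolution 1 (igraph 0.11.9, no batch correction). Clusters were called beta-like, alpha-like and so on from markers fixed beforehand. A threshold of 0.5 on the marker score and a minimum of 5 detected markers, both set after the data were seen, left clusters unnamed. Endocrine clusters were all clusters not named for a nonendocrine class, unnamed ones included.

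A barcode was called in a cell when its count was at least 5 and at least 5 times the library's background level of that barcode. The background was the median count over the library's cells or, where that median was under 5, the larger of it and the Poisson mean that the share of cells with a count of 0 implies. This rule replaced the planned minimum of 2 counts for the added comparisons, because cells with 0 barcode counts were almost absent from the pool libraries. Shares of cells have exact Clopper-Pearson intervals at a level of 0.95, and a share of 0 has a limit of 3 counts. Both cover counting error only. To compare shares across depths, cells were thinned to 5000 UMIs and shallower cells left out.

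Raw UMI counts were summed per unit and arm (at least 20 cells) and tested with edgeR 4.0.16 in R 4.3.3 (TMM, filterByExpr, quasi-likelihood test, Benjamini-Hochberg adjusted p, threshold 0.05). Analysis unit, or donor and virus pair, was a block. The pairing comes from the labels (same donor and virus) or from both arms coming from the same library. DESeq2 1.42.0 was the other tool. Gene lists fixed beforehand were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the lists. Comparisons between pool and control libraries had 1 unit per preparation, all of donor B, and no test. A gene counted there as higher or lower at a fold of at least 2 in the same direction in both preparations and a mean of at least 20 CPM. List medians were set against 10000 random lists matched on mean expression.

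The designs, gene lists and rule for named genes were written before the data were examined. The rule takes the 10 largest changes each way past the threshold with a mean log2 CPM of at least 5 and 1 direction in every pair, up to 4 members of each list by p, and for each factor its own gene and the 3 genes with the smallest p each way. For pool against control it takes the 10 largest each way and up to 4 members of each list. The text prints a part of the genes so named. For single barcodes, the members of gene lists, and for cells with several calls the list members, were chosen after their values were seen. The comparisons of barcode calls (any call or BFP alone against no call, and each factor among cells with exactly 1 call) were added after the data were seen. The same holds for clusters rebuilt on the marker genes alone, for clusters named by score alone, for matching cells on total UMIs in 10 bins per unit, for other references and multiples of the background, and for values without the 10 cells with the most UMIs of a gene. The alternatives set beforehand were DESeq2, its size factors, no filter, no block, each unit left out, doublets kept, 10% mitochondrial counts, resolution 0.5, the duplicate left out, other barcode minimums and sums per donor. XIST, TSIX and Y-linked genes were left out of every table, and the 15 factors were kept in it.

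Each tested comparison was run on simulated counts with 200 changed genes, and the comparisons of factors were simulated for BACH2 only. For FADplus against islet (13959 genes) edgeR recovered 67.1% of 2-fold and 94.1% of 4-fold changes with 12 false calls. The shares were 65% and 92.9% with 14 false calls for any call against no call (15717 genes), and 14.7% and 98.2% with 2 for the BFP call (12715 genes). For BACH2 they were 77.9% and 92.4% with 10 against the other factors (12912 genes), and 63.5% and 86.1% with 5 among single barcodes (14772 genes). Recovery for the other factors, some with fewer units, is not known. Gene positions are from the GENCODE annotation of hg38. The files give gene symbols without strand or read details, so near-identical genes (HSPA1A and its paralog, the metallothioneins, histones) and overlapping or antisense genes are uncertain.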

Results

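Gene expression was measured in single islet cells to ask what each of the 15 factors does when an adenovirus delivers it. The pool virus state had 2 FADplus units and 2 islet units, 1 of each from each donor, and the control state had 1 FADplus and 1 islet unit, both from donor B. The pool islet unit of donor B joins a library and its technical duplicate. The libraries held between 2316 cells (pool FADplus replicate 1) and 3449 cells (pool islet replicate 1), with 44100407 to 71899883 UMIs each. Median UMIs per cell were 16252 and 16233 in pool FADplus replicates 1 and 2, 13405, 16582 and 15864 in pool islet replicates 1, 2 and 3, 15908 in the control islet library and 24623 in the control FADplus library. After the filters 2294, 3199, 3393, 2318, 2667, 2939 and 2487 cells remained in the same order.

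The cell classes differed between the preparations, and beta-like cells were more frequent in FADplus, as its source implies. Beta-like cells made up 19.6% of the pool FADplus unit of donor A (exact 95% interval 18.0 to 21.3) against 8.4% (7.49 to 9.38) of the pool islet unit. In donor B they made up 25.3% (23.8 to 26.8) against 10.5% (9.63 to 11.4) in the pool state, and 41% (39.1 to 43.0) against 3.3% (2.68 to 4.01) in the control state. The difference between the preparations was 14.8 points in the median of the 3 pairs (SD 14.4) and had the same sign in each. An exact sign-flip test on 3 pairs cannot reach the threshold. The FAD+ enrichment can set these shares by itself. Alpha-like cells were 65% of the control islet unit and 3.74% of the control FADplus unit, and stellate-like cells were 0.17% and 30.6%. The higher stellate-like share in control FADplus is not implied by a source of enriched beta cells. Unnamed clusters held 0.953% and 8.61% of the control islet and FADplus cells but 30.9%, 52.1%, 64.4% and 66.8% of the cells of the pool units, so beta-like and alpha-like shares of the virus states were not compared. Different clusters also made up the beta-like class. Cluster 25 held 95.9% of it in the control islet unit and cluster 8 held 86% in the control FADplus unit, while clusters 2, 15 and 24 held most of it in the pool units.

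Viral barcode counts were found in nearly every cell of the pool libraries. At least 2 barcode counts were found in 96.3% (96.0 to 96.6) of 13871 pool cells and in 30.1% (28.8 to 31.3) of 5426 control cells. The control value came from the control FADplus library, in which 65.3% of cells reached 2 counts, almost all of the BFP barcode, against 0.238% in the control islet library. After thinning to a fixed depth the shares were 89.4% and 7.34%. In the donor B pool libraries the background level of the BFP barcode was 11 to 14 counts per cell, so 2 counts do not show that a cell carried a virus. A call above the background was made in 83% of pool cells and 4.61% of control cells. A factor barcode was called in 69.8% (69.1 to 70.6) of pool cells and in 0.018% of control cells. The BFP barcode was called in 15.1% and 4.59%. Exactly 1 barcode was called in 62.4% of pool cells and 2 or more in 20.6%. Only beta-like cells had barcode shares above 96% in all 4 pool units, at 98.9% and 96.5% in donor A. In the pool FADplus unit of donor A the share fell to 70.4% (61.2 to 78.6) in ductal-like cells and 48.5% (40.7 to 56.4) in endothelial-like cells, whose median depth was 9537 UMIs against 20838 in beta-like cells.

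Barcodes did not fall into cells independently of each other. Of 164 endocrine pool cells with a BNC2 call, 99.4% (96.6 to 100) also had a ZRANB3 call, against 3.31% of the other cells. ZRANB3 was also called in 94.4% of 179 MYT1L cells. FOXO1 was called in 95.9% (93.6 to 97.6) of 441 EBF1 cells and BACH2 in 98.3% (96.1 to 99.5) of 299 TSHZ2 cells. RARB and ZNF385D shared cells in both directions, at 85.7% of 726 RARB cells and 85.2% of 730 ZNF385D cells, and GAS7 was called in 66.7% and 64.1% of these. RFX7 was called in 30.4% of 1039 CUX2 cells and CUX2 in 31% of 1018 RFX7 cells. Over the pool units with at least 20 such cells the ranges were 98.4 to 100% for BNC2 with ZRANB3, 93.2 to 98.9% for EBF1 with FOXO1 and 69.1 to 93.2% for RARB with ZNF385D. They were wider for GAS7 in RARB cells (53.3 to 76.2%) and ZNF385D cells (48.7 to 75%) and for CUX2 in RFX7 cells (21.3 to 58.1%). Few cells were therefore left with the BNC2 (0), MYT1L (4), TSHZ2 (4), EBF1 (16), RARB (29) or ZNF385D (59) barcode alone, against 1362 for GAS7 and 1745 for BFP.

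**Figure D1:**
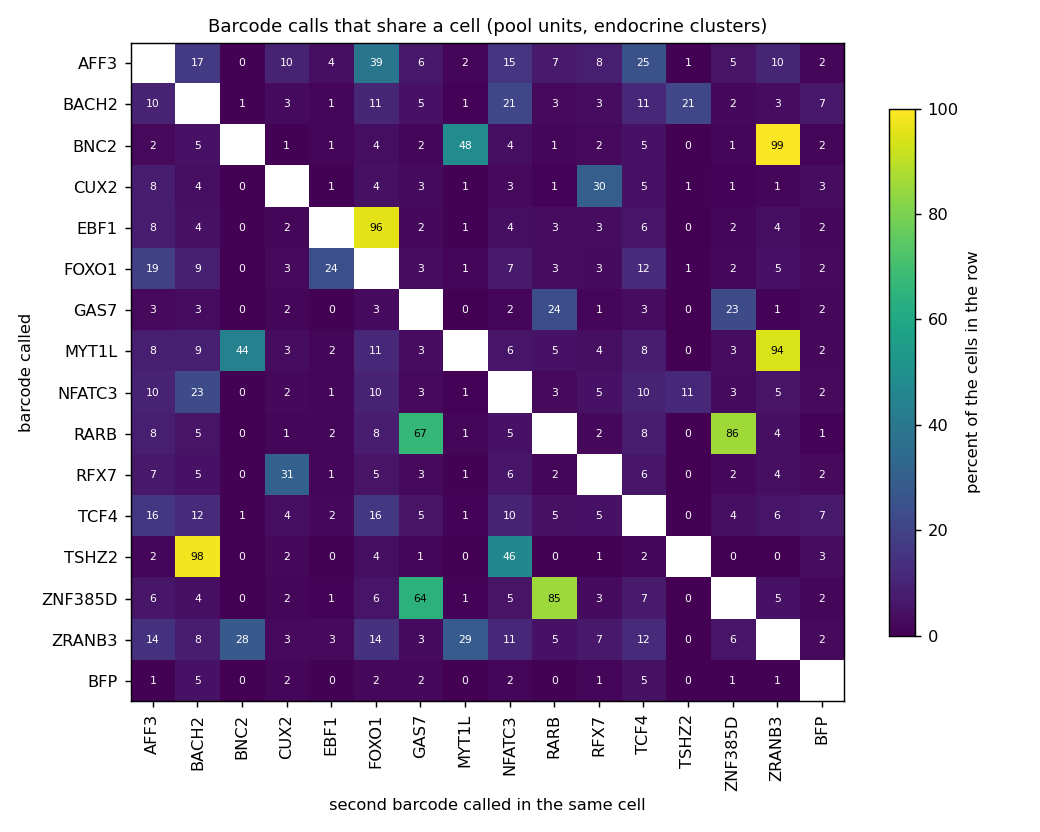
Percent of the endocrine pool cells called for the barcode of a row that were also called for the barcode of a column, with colour from dark purple (0) to yellow (100). BNC2 and MYT1L cells were also called for ZRANB3 (99.4% and 94.4%), EBF1 cells for FOXO1 (95.9%) and TSHZ2 cells for BACH2 (98.3%).

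The factor's own transcript was higher in cells with its barcode. In the planned comparison of beta-like cells with at least 2 counts of a barcode against cells with another, 11 of 13 fitted factors had a higher own transcript, from a log2 fold of 0.39 ± 0.141 (SE, adjusted p = 0.026) for TCF4 and 0.40 ± 0.161 (adjusted p = 0.0324) for FOXO1 to 7.20 ± 0.454 (adjusted p = 2.17e-09) for AFF3. NFATC3 (0.27, adjusted p = 0.0957) and ZNF385D (0.07, adjusted p = 0.705) did not pass. With calls above the background in all endocrine clusters, all 15 factors passed, BNC2 at 5.61 ± 0.64 and EBF1 at 5.24 ± 0.311 among them. In cells with exactly 1 call, AFF3 rose by 9.39 ± 0.219, ZRANB3 by 5.21 ± 0.209, GAS7 by 4.47 ± 0.149, CUX2 by 3.42 ± 0.17, RFX7 by 3.32 ± 0.213, BACH2 by 3.23 ± 0.149, TCF4 by 2.63 ± 0.148, FOXO1 by 1.65 ± 0.18 and NFATC3 by 1.26 ± 0.146, while ZNF385D (0.96 ± 0.526, adjusted p over factors = 0.0776) did not pass. A UMI of the AFF3 transcript was found in 97.5% of AFF3-called cells against 11.9% of cells with no call, and the shares were 91.6% and 14.4% for GAS7, 65.1% and 6.61% for ZRANB3 and 43.2% and 23.1% for FOXO1. Transcripts of other pool factors were also higher in some single-call cells. RFX7 stood 3.04 ± 0.219 higher in CUX2 cells, MYT1L 3.36 ± 0.287 higher in ZRANB3 cells, RARB 3.07 ± 0.67 higher in ZNF385D cells (2 units) and EBF1 2.34 ± 0.515 and TCF4 1.60 ± 0.161 higher in FOXO1 cells. The other such transcripts were BNC2 in ZRANB3 cells (2.5 ± 0.754) and TSHZ2 in BACH2, BFP and CUX2 cells (1.09 ± 0.306, 0.97 ± 0.258 and 0.94 ± 0.285).

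**Figure D2:**
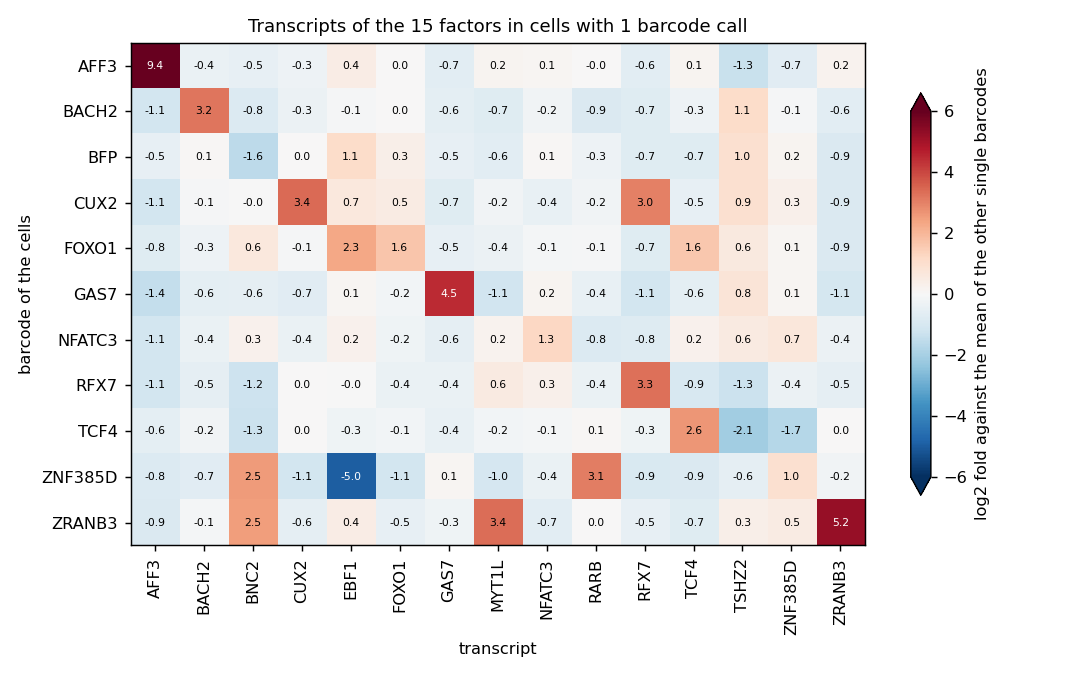
Log2 fold (edgeR) of each factor's transcript (columns) in cells with 1 barcode call (rows) against the mean of the other single barcodes, with colours saturating at the ends of the scale. The diagonal is the highest value in the rows for AFF3 (9.39), ZRANB3 (5.21) and GAS7 (4.47), and the CUX2 row is also high for RFX7.

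Cells with the CUX2 barcode carried an antioxidant program. HMOX1, the heme oxygenase that NRF2 induces (chromosome 22, 35380361 to 35394214), stood 5.74 ± 0.217 higher on the log2 scale (adjusted p = 6.44e-21, higher in 4 of 4 units) than in the mean of the other single barcodes, with 1026 ± 556 CPM (SD, n = 4) against 37.8 ± 12.2 CPM in cells with no call. NQO1 rose by 2.92 ± 0.185, the iron store FTH1 by 2.36 ± 0.144, the selective autophagy receptor SQSTM1 by 2.20 ± 0.143 and the iron-binding LCN2 by 4.83 ± 0.264. Of 15 antioxidant and NRF2 targets 10 rose and none fell (median 0.80, adjusted p = 3.13e-22), a call that held with an estimated correlation (adjusted p = 0.000208). The kinase gene MKNK2 rose by 2.80 ± 0.131 and C12orf75 fell by 1.40. Of 22 chemokine and NF-kB genes 12 also rose, as did 10 of 20 p53 targets, at adjusted p = 0.162 and 0.213 with an estimated correlation. Against cells with no call HMOX1 was 4.69 ± 0.404 higher, LCN2 only 2.12 ± 0.395, and the list's median was 0.768, with adjusted p = 0.0549 at an estimated correlation. Without the 10 cells with the most UMIs the log2 ratio of HMOX1 was 4.58, whereas that of RFX7 fell from 2.61 to 0.07.

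Cells with the BACH2 barcode showed the opposite for this list and a rise of chaperones. The rise is not particular to BACH2, as heat shock genes were also higher in cells called for BFP alone. BACH2 is known as a repressor of antioxidant genes. NQO1 fell by 3.23 (SE 0.373, adjusted p = 1.33e-07, lower in 4 of 4 units), to 1.3 ± 1 CPM against 13.5 ± 5.72 in cells with no call. GSTP1, a glutathione transferase, fell by 1.27. Of the 15 antioxidant and NRF2 targets 10 fell and 1 rose (median -0.84, adjusted p = 2.47e-11, and 0.00868 with an estimated correlation). All 13 heat shock genes rose (median 2.15, adjusted p = 2.88e-32, and 0.00868 with an estimated correlation), with HSPA6 at 3.95 ± 0.389 and the collagen chaperone gene SERPINH1, which is outside the list, at 3.14 ± 0.251. In beta-like cells alone, which leave out the unnamed cluster 19 led by HSPA6 and BACH2, the heat shock median was 0.297 with no member past the threshold in edgeR, HSPA6 was at -0.44 and SERPINH1 at -0.01. The antioxidant list had a median of -1.156 there, with 6 of 14 genes lower (camera with an estimated correlation, adjusted p = 0.00782). In beta-like cells of clusters built on the marker genes alone all 13 rose (median 2.48), while the antioxidant list had an adjusted p of 0.286 with an estimated correlation. Against cells with no call the heat shock and antioxidant lists had medians of 2.31 and -0.913 and an adjusted p of 0.0555 each with an estimated correlation. Of 20 cholesterol synthesis genes 12 rose and none fell (median 0.63, adjusted p = 0.0322 with an estimated correlation), among them HMGCS1 at 1.40 ± 0.243, but this list did not hold against cells with no call either. UCHL1 fell by 1.39.

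Among the factors with single-call cells, FOXO1, RFX7 and TCF4 had the most calls in this comparison, which was chosen after the data were seen, but at most 2 each in the planned one. In FOXO1 cells 3796 genes were higher and 3468 lower of 14773. Of 20 p53 targets 15 fell (median -1.21), with CDKN1A at -2.08 ± 0.208 and the apoptosis gene BBC3 at -2.23 ± 0.186, and 15 of 19 glycolysis genes fell (median -1.33), with GAPDH at -1.51 ± 0.187. Ribosomal protein genes rose (41 of 46, median 0.70). None of the 3 lists held with an estimated correlation (adjusted p = 0.338 for each). The cell cycle kinase assembly factor MNAT1 rose by 2.60 ± 0.122 and the endosome gene CHMP2B by 2.02 ± 0.099, and PPP1R14B fell by 2.39. In RFX7 cells 3226 genes were higher and 2697 lower. Cell cycle genes rose (13 of 21, with 2 lower, median 1.40, adjusted p = 0.0609 with an estimated correlation), among them TOP2A at 5.12 ± 0.304 and UBE2C at 6.31 ± 0.34, with TROAP at 6.85 ± 0.267 and SATL1 at 6.99 ± 0.276 outside the list. Against cells with no call these 4 were higher by less, TOP2A by 3.40 ± 0.423, UBE2C by 3.80 ± 0.486, TROAP by 5.52 ± 0.429 and SATL1 by 3.19 ± 0.417. TOP2A remained low, at 33.4 ± 14.9 CPM against 2.7 ± 2.12 in cells with no call. Ribosomal protein genes fell (40 of 46, median -0.69, adjusted p = 0.579 with an estimated correlation), with RPS14 at -1.03 ± 0.098, and DRAP1 was lower too (-1.5 ± 0.137). In TCF4 cells 3140 genes were higher and 2622 lower. The ephrin gene EFNA3 rose by 4.15 ± 0.168, the neurexophilin gene NXPH4 by 4.85 ± 0.199 and the glutathione transferase gene GSTM3 by 3.32 ± 0.132. Against cells with no call they were higher by less, at 3.59 ± 0.307, 3.51 ± 0.353 and 2.33 ± 0.226. MOAP1 fell by 2.47 and the adaptor gene APPL1 by 2.21.

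The other factors had fewer calls among single-call cells. In NFATC3 cells (1371 higher, 314 lower) RCAN1, a feedback inhibitor of calcineurin and a known NFAT target, rose by 3.05 ± 0.252 (adjusted p = 8.15e-11, 4 of 4 units), ADTRP by 4.24 ± 0.327, the kinase gene MAP2K6 by 2.94 ± 0.204 and LBH by 2.80 ± 0.213, and CKB fell by 1.09. Against cells with no call these rises were smaller, RCAN1 at 2.23 ± 0.372, ADTRP at 2.23 ± 0.462, MAP2K6 at 2.08 ± 0.307 and LBH at 1.42 ± 0.311. MDM2 rose by 1.35 ± 0.141 and 9 of 20 p53 targets were higher (adjusted p = 0.439 with an estimated correlation). In GAS7 cells (634 higher, 239 lower), which came from the 2 units of donor B, TMOD1, an actin capping gene, rose by 1.81 ± 0.198 and HNRNPD fell by 0.96. There 9 of 15 antioxidant and NRF2 targets rose (median 1.05, adjusted p = 0.0102 with an estimated correlation, which did not hold against cells with no call), with GCLM at 1.32 ± 0.165. The metallothionein MT1X rose by 2.35 ± 0.372, but did not pass against cells with no call (1.75 ± 0.511, adjusted p = 0.0648). In ZRANB3 cells (1500 higher, 798 lower, 3 units) CTXN1 rose by 3.10 ± 0.181 and VAMP8 fell by 1.36. In AFF3 cells (782 higher, 244 lower) the serotonergic factor gene FEV stood 2.65 ± 0.313 higher and KRT18 0.90 lower (-0.90), and alpha cell markers were higher (12 of 14, adjusted p = 0.38 with an estimated correlation). Against cells with no call AFF3 cells had only 7 genes higher and 8 lower, with FEV at 0.57 (adjusted p = 0.793) and KRT18 at -0.60 (adjusted p = 0.185). The 59 ZNF385D cells had 82 genes higher and 9 lower. Their neuropeptide gene NMB was 3.51 ± 0.245 higher. The 10 highest cells held 70.7% of the NMB UMIs, and the log2 ratio fell from 3.25 to 1.85 without them. They held 99.7% of the OXT and 90.9% of the ISG15 UMIs behind folds of 6.34 and 3.13. The interferon list, which holds ISG15, was higher there in 8 of 33 genes (adjusted p = 0.0124 with an estimated correlation), and did not hold against cells with no call.

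**Figure D3:**
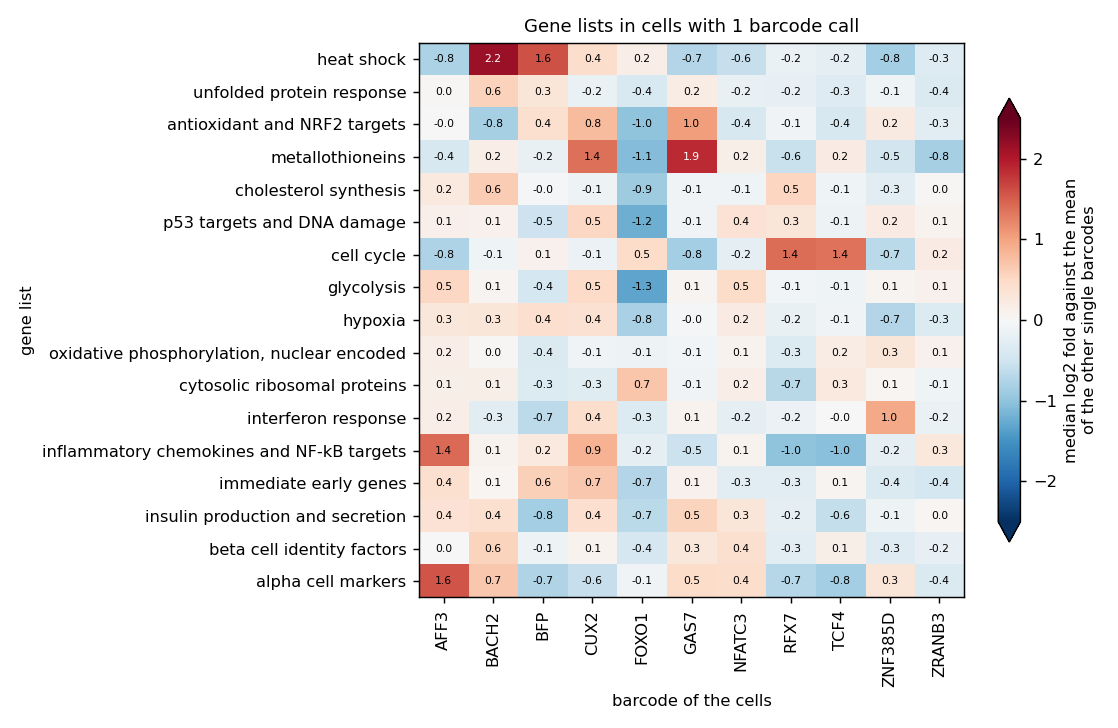
Median log2 fold (edgeR) of 17 fixed gene lists (rows) in cells with 1 barcode call against the mean of the other single barcodes (columns). Heat shock genes were high for BACH2 (2.15) and BFP (1.58), antioxidant and NRF2 targets for CUX2 (0.80) and GAS7 (1.05), and p53 targets and glycolysis were low for FOXO1 (-1.21 and -1.33).

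Factors with few single-call cells were compared through all of their called endocrine cells, which mostly hold a second barcode, so the factors that share cells are not separated. In 726 RARB cells the retinoic acid hydroxylase gene CYP26A1 stood 4.31 ± 0.316 higher (adjusted p = 6.22e-06) and DHRS3 0.79 ± 0.122 higher, while the retinoic acid response genes CRABP2, TGM2, RARRES1 and RARRES3 did not pass (0.12, -0.10, -0.18 and -0.98). FGF19, a secreted growth factor gene, rose by 6.34 ± 0.17 and CCND1 by 3.77 ± 0.126, and IL11 was lower by 3.55. The lower IL11 is not particular to RARB, as the value was -3.42 in AFF3, -3.65 in GAS7 and -3.58 in ZNF385D cells. The cells compared with include those called for BFP, in which IL11 was higher than in cells with no call. In EBF1 cells CTH rose by 3.93 ± 0.169, LRRN3 by 4.07 ± 0.176 and AGR2 by 4.38 ± 0.191. In MYT1L and BNC2 cells IFI30 rose by 4.17 ± 0.232 and 4.05 ± 0.175 and ZRANB3 by 4.65 ± 0.215 and 5.35 ± 0.204. In TSHZ2 cells the lactate exporter gene SLC16A3 rose by 2.24 ± 0.109 and BACH2 by 3.05 ± 0.15.

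Of the 36809 calls over the 11 single barcodes 21861 were higher and 14948 lower. DESeq2's size factors changed the split from 1482 higher and 689 lower to 1187 and 851 for BACH2 and from 634 and 239 to 441 and 293 for GAS7. Leaving out pool islet replicate 2 left 22648 calls, matching cells on total UMIs left 17217, and beta-like cells alone, in which 4 barcodes could be fitted, gave 5740. The planned comparison in beta-like cells at a minimum of 2 counts gave 4288 calls over 13 factors (2494 higher, 1794 lower), of which NFATC3 (801 and 647), ZRANB3 (897 and 502), TSHZ2 (332 and 322), MYT1L (329 and 230) and RARB (93 and 82) made up most. AFF3 had 1, BACH2 7, CUX2 29, GAS7 3, RFX7 2 and ZNF385D 11. FOXO1 and TCF4 had 0 in edgeR, with 1353 and 1097 genes at an unadjusted p under 0.05 and 23 and 14 calls in DESeq2. The fit without the block gave 516 calls, leaving out pool FADplus replicate 2 or pool islet replicate 1 gave 2327 and 2617, and a minimum of 5 counts gave 10157.

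Cells called for BFP alone differed from cells with no call in the same units. None of the gene lists named here held with an estimated correlation (adjusted p = 0.805 for heat shock, insulin production, interferon response and alpha markers). The comparison was added after the data were seen, and the labels do not state what the BFP barcode marks. IL11 (chromosome 19, 55364389 to 55370463), a cytokine gene, rose by 4.25 ± 0.362 (adjusted p = 0.00301, 4 of 4 units), to 171.9 ± 111 CPM (SD, n = 4) against 7.89 ± 7.59. All 13 heat shock genes rose (median 1.79), with HSPA6 at 3.32 ± 0.567, HSPA1A at 3.24 ± 0.274, BAG3 at 3.37 ± 0.318 and HSPH1 at 2.52 ± 0.243, as did the small chaperone CRYAB at 3.74 ± 0.434 and the tubulin gene TUBA1C at 2.84 ± 0.214, which are outside the list. Of 32 genes of insulin production and secretion 22 fell and none rose (median -1.27), with the beta cell glucose-6-phosphatase gene G6PC2 at -2.42 ± 0.273, the KATP channel gene ABCC8 at -2.20 ± 0.201 and the calcium channel gene CACNA1A at -1.85 ± 0.227. FXYD2 (-3.14 ± 0.37), PPP1R1A (-2.70 ± 0.287) and the maturity marker UCN3 (-2 ± 0.402) fell too, whereas the beta cell factor NKX6-1 rose by 1.35 ± 0.309. Of 31 interferon response genes 18 fell, IFI6 at -2.48 ± 0.254 among them. The AP-1 gene FOSL1 rose by 2.1 ± 0.287, the redox gene TXNRD1 by 1.84 ± 0.202 and TRIB3 by 1.55 ± 0.17. Alpha cell markers were lower in these cells (11 of 13, median -2.02). In beta-like cells the medians were 1.11 for heat shock and -1.56 for insulin production.

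**Figure D4:**
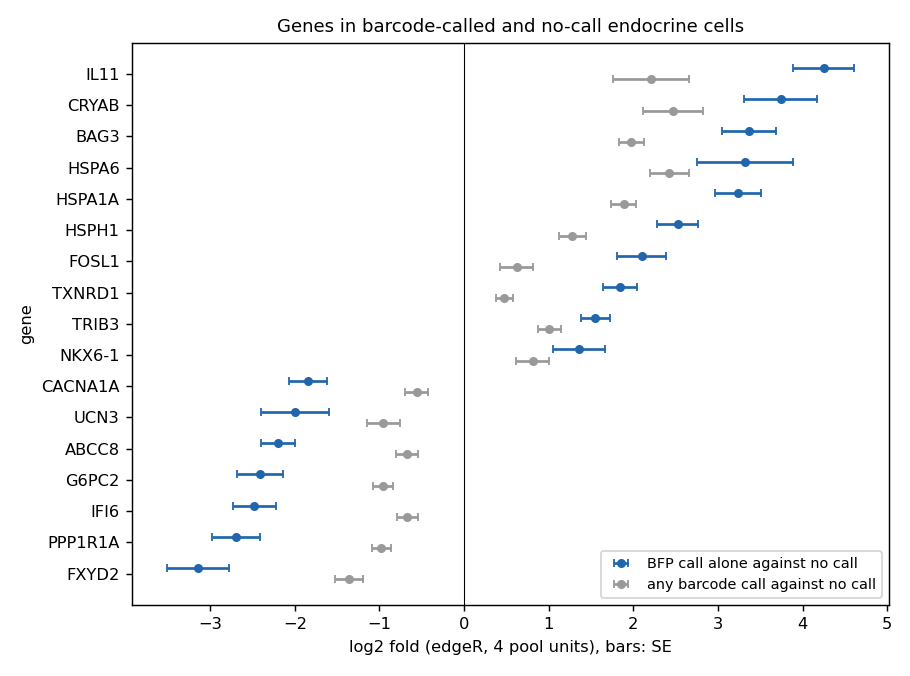
Log2 fold ± SE (edgeR, 4 pool units) of 17 genes in endocrine cells called for BFP alone (blue) and in cells with any barcode call (grey) against cells with no call. IL11 and the chaperone genes lie to the right (4.25 for IL11 with BFP) and secretory and interferon genes to the left (-2.42 for G6PC2).

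In all, 2179 genes were higher and 2235 lower of 12715 in BFP cells. By camera with the preset correlation 9 of 29 lists passed. With an estimated correlation 0 did (adjusted p = 0.805 for heat shock and for insulin production), and by fry 4 did (adjusted p = 0.029 for each of these). Leaving out pool islet replicate 2 gave 1613 calls and leaving out pool FADplus replicate 2 gave 2189.

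Cells with any call, BFP cells among them, were compared with the same cells with no call, so this comparison is not independent of the one for BFP. HSPA6 rose by 2.43 ± 0.226, BAG3 by 1.98 ± 0.146 and CRYAB by 2.47 ± 0.356, and 12 of 13 heat shock genes rose (median 0.87, adjusted p = 0.412 with an estimated correlation). The retinoic acid target CYP26A1 rose by 3.73 ± 0.544. Of 34 genes of insulin production and secretion 17 fell (median -0.41, adjusted p = 0.412 with an estimated correlation), with CHGB at -1.27 ± 0.173, SCG5 at -1.14 ± 0.153 and G6PC2 at -0.96 ± 0.119. Of 14 alpha cell markers 13 fell (median -1.23, adjusted p = 0.475 with an estimated correlation), among them TM4SF4 at -1.81 ± 0.28, as did the ceruloplasmin gene CP at -1.88 ± 0.263. The stress gene DDIT4 rose by 0.96 ± 0.101, but was at -0.31 in beta-like cells. In total 1474 genes were higher and 1630 lower of 15717. Without the block for the unit 1 gene passed, beta-like cells alone gave 545 calls, and leaving out pool islet replicate 1, pool islet replicate 2 or pool FADplus replicate 2 gave 1321, 1562 and 1413.

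Few genes passed between beta-like cells of the FADplus and islet preparations. Counts were not corrected for RNA from other cells of a library, so markers of other cell types cannot be assigned to the beta-like cells themselves. Of 10 stellate markers 4 were higher (median 2.62), with BGN at 4.36 ± 0.527 (adjusted p = 0.0145, 3 of 3 pairs), COL1A1 at 3.17 ± 0.356, TIMP3 at 3.13 ± 0.398 and SPARC at 3.12 ± 0.376. The alpha marker LOXL4 (-2.55 ± 0.272, adjusted p = 0.0145) and the metallothionein gene MT1A (-1.20 ± 0.177, adjusted p = 0.0426) were lower. The alpha marker GC (-1.90 ± 0.31, adjusted p = 0.0739) and the acinar protease gene CTRB2 (-3.51 ± 0.566, adjusted p = 0.071) did not pass, and CTRB2 was higher in 1 of the 3 pairs. Of 34 insulin production genes and 19 beta cell identity factors none passed in edgeR (median -0.13 and -0.15), adjusted over the list alone also none. In all 11 of 13959 genes passed (6 higher, 5 lower), none with a mean log2 CPM of 5 or more, with 1368 at an unadjusted p under 0.05 and 16 calls in DESeq2. By camera 20 of 29 lists passed at the preset correlation and 0 with an estimated one (adjusted p = 0.378 for stellate and alpha markers), and by fry 0. Without the pair as a block 0 genes passed (111 at an unadjusted p under 0.05), without pair 1 there were 26 and without pair 2, the control pair, there were 60, and keeping the marked doublets left 6.

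Beta-like cells of the pool libraries differed from those of the control libraries of the same donor in p53 targets, some immediate early genes and some secretory genes. There is 1 unit per virus state and preparation and no test was run. The control FADplus library had a BFP barcode count in 86.48% of its cells, and cells called for BFP stayed in its sums. It therefore cannot be taken as free of virus. Cluster 2 held 80.8% of the pool FADplus cells compared and 78.2% of the pool islet cells. Its top genes by fold over the other clusters were led by GAS7 and included TRIB3. Most control cells were in other clusters, and pool cells of unnamed clusters were left out. The comparison is thus largely one of cluster 2 with control cells. Values are for FADplus and then islet. The sums held 809 pool and 1020 control cells in FADplus, but 522 pool and only 97 control cells in islet. Islet folds can therefore rest on few control counts, such as 11 for FDXR. Of 17 p53 targets above the expression minimum 14 were higher and 1 lower, with medians of 1.63 and 1.83, above all 10000 random lists in both. FDXR stood at 2.64 and 2.37, PHLDA3 at 2.32 and 3.17, the cytokine gene GDF15 at 2.21 and 2.57 and BBC3 at 2.20 and 2.48. Of 18 immediate early genes 8 were lower (medians -1.02 and -1.03), with FOSB at -3.10 and -4.24, EGR3 at -3.40 and -4.08 and FOS at -2.02 and -2.32. EGR4 (-3.69 and -5.72), which is outside the list, was lower too. Of 10 chemokine and NF-kB genes 6 were lower (medians -1.38 and -1.56), with TNFAIP3 at -1.69 and -1.83. Insulin production genes had medians of -0.58 and -0.71, below all random lists, with 4 of 24 past the rule. G6PC2 was at -1.27 and -1.33, ABCC8 at -1.08 and -1.12, CHGB at -1.05 and -1.96 and the beta cell factor MAFA at -1.18 and -1.03. Of 24 unfolded protein response genes 5 were higher (medians 0.58 and 0.85), the chaperone gene HSPA5 at 1.49 and 1.58 and TRIB3 at 1.93 and 2.48 among them, and HMOX1 was at 2.77 and 3.27.

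By the smaller of the 2 folds the pool factor GAS7 was the highest (9.95 and, against 2 control counts, at least 8.25, with 382 and 324 CPM in the pool units), followed by the angiogenic gene ANGPT2 (5.76 and 6.68). IL11 was at 4.21 in FADplus, and at least 6.78 in islet against 0 control counts, with the floor of 3 counts. Markers of other cell types were lower in the pool units, with GCG at -1.87 and -3.00, TM4SF4 at -2.47 and -4.38 and COL1A1 at -3.91 and -3.16, where the islet value rests on 3 and 6 counts. These counts too were not corrected for RNA from other cells of a library. CTRB1 was at most at -8.86 in islet against 1 pool count, and in FADplus at most -4.90 against 0 pool counts. By the rule 529 genes were higher and 81 lower of 5362. The median of all genes was 0.402 and 0.489 higher. With TMM-scaled CPM, which moved it to -0.108 and -0.001, the rule gave 110 higher and 250 lower. In pool cells with no call, of which there were 56 and only 16, the rule gave 189 genes, and there the islet value of G6PC2 was 0.64 and that of COL1A1 1.88.

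**Figure D5:**
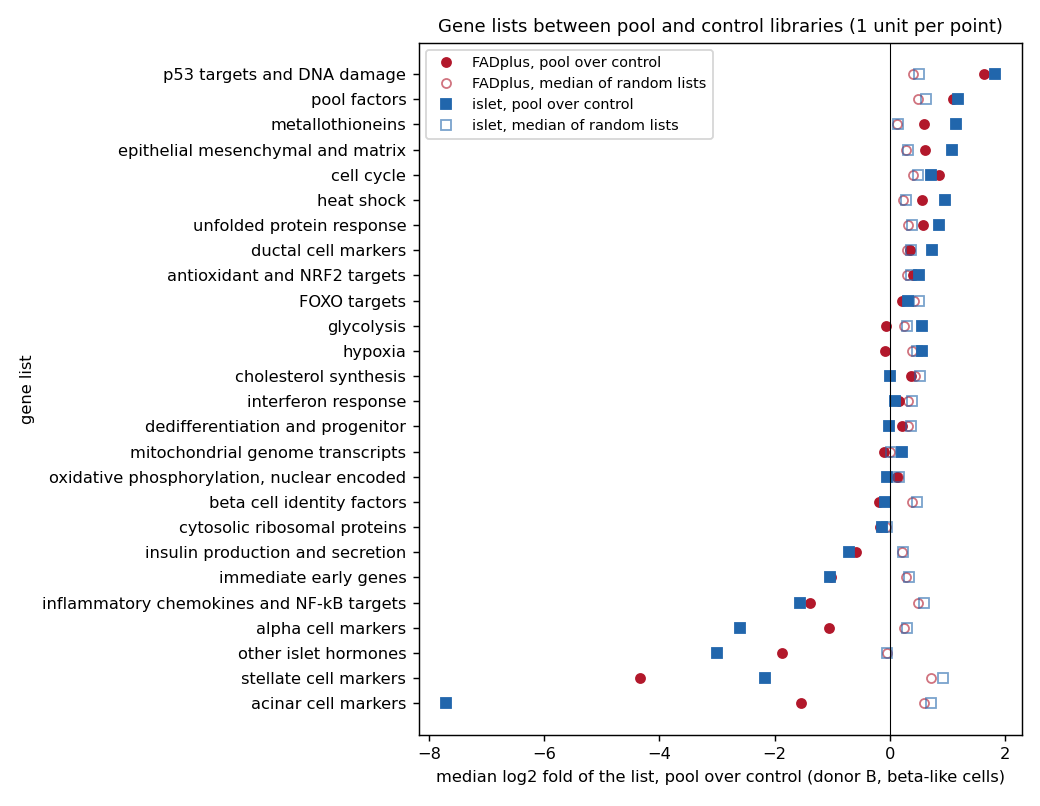
Median log2 fold of the fixed gene lists between pool and control beta-like cells of donor B, with 1 filled point per preparation and, as open points, the median of random lists matched on mean expression. p53 targets were highest (1.63 and 1.83), and acinar, stellate and alpha markers, other islet hormones, chemokine and immediate early genes were lowest.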

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

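Of the tests in this part, the one inside the control FADplus library, those on HMOX1 in RFX7 cells and on the 10 highest cells, the division of CUX2 cells by RFX7 barcode counts, and both on p53 targets were chosen after the result was seen. No group has 4 to 10 samples, so no sample was tested for standing apart.

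A BFP barcode count was found in 86.48% of the 2530 cells of the control FADplus library, whose virus label is NA, against 0.33% of the control islet library. Counts in the 32 barcode rows named for guides were found in 1.64% (1.44 to 1.86) of pool cells and 0.107% (0.0394 to 0.234) of control cells.

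Some genes moved one way in both units of donor A and the other way in both units of donor B, a difference that was not tested. In cells with any call against no call the donor A minus donor B difference of the mean log2 fold was -2.01 for PYY (-1.54 and 0.48), -0.57 for ERO1B, -0.63 for P4HA1, -1.15 for TXNIP and -0.64 for IGFBP5. In BFP cells against no call it was 6.57 for PPY (2.64 and -3.93) and 1.31 for MT1M (0.16 and -1.15).

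In BFP cells heat shock genes were higher and insulin production genes lower than in cells with no call. A difference in depth is argued against, because matching on total UMIs left the heat shock median at 1.82 (1.79 unmatched). Another mix of endocrine cells cannot be told apart. The insulin production median was -1.70 in beta-like cells of marker-built clusters, past the bound set against a mix. However, the markers that built those clusters include genes of that list, G6PC2 among them, and alpha cell markers also fell in BFP cells. Heat shock was not part of that test, and its median in beta-like cells was 1.11. A property of the pool libraries alone is argued against by the control FADplus library, where the heat shock median between 173 BFP and 1409 no-call cells was 1.34, although that of insulin production was -0.46. A response to the virus or to BFP may remain as a hypothesis. It was not tested whether the no-call cells of the pool units are uninfected. Cells given a virus without BFP, beside cells given none, would test it.

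RFX7 and HMOX1 transcripts were higher in cells with the CUX2 barcode alone. For RFX7, a few cells can account for the rise, as the log2 ratio fell to 0.07 without the 10 highest cells, and 25.56% of CUX2 cells had at least 2 RFX7 barcode counts, against 3.12% of cells called for 1 other factor. RFX7 was at 18.4 CPM in CUX2 cells with 0 RFX7 barcode counts (18.7 in no-call cells), at 546.5 with 1 and at 106.8 with at least 2. Without the 10 highest cells, none of which had 0 RFX7 barcode counts, it was at 29.7 and 33.2. A second infection cannot be told apart from other sources, because the share of 25.56% lies between the bounds set for either answer. Neither a few cells nor the RFX7 virus by itself accounts for HMOX1, which was at -0.75 in RFX7 cells and at 4.58 in CUX2 cells without the 10 highest cells. HMOX1 was also at 794.6 CPM in CUX2 cells with 0 RFX7 barcode counts, against 38.8 in no-call cells. Whether a virus of another barcode below its cutoff was present was not tested. For a mixture of viruses under the CUX2 barcode, a lower share of RFX7 UMIs in CUX2 cells with a CUX2 UMI was predicted. The share was 28.7% there, against 8.9% of those without. This cannot decide, because cells with more barcode counts can hold more of either UMI. The median CUX2 barcode count was 28 in CUX2 cells with 0 RFX7 barcode counts, 42 with 1 and 80 with at least 2. An effect of CUX2 on HMOX1 may be a hypothesis, which was not tested. Cells given the CUX2 virus by itself would test it.

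p53 targets were higher in pool than in control beta-like cells. Scaling by total counts is argued against, as the list stood at least 1.23 above the median of all genes in both preparations. A difference between the libraries that does not depend on the virus in the cell cannot be told apart, because each virus state has 1 unit per preparation. In all endocrine clusters of the FADplus preparation the list's median in the 273 pool cells with no call stood 0.53 above control cells with no call (-0.21 for the median of all genes), and that in called pool cells 1.81 above. BFP cells stood 0.54 above no-call cells inside the control FADplus library.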

How the results depend on the processing

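The comparisons of barcode calls and their settings, the marker-built and score-named clusters, the no-call cells and the matching on UMIs were chosen after the data were seen. Over all settings the named genes kept direction and side of the threshold in 354 of 359 values for BFP against no call, 75 of 112 for FADplus against islet, 173 of 189 for any call, 202 of 229 for factors at 2 counts, 1043 of 1059 for single barcodes and 346 of 396 for pool against control. The cause of the changes below was not tested.

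FADplus against islet (11 genes) gave 271 without the filter, 6 with doublets kept, 20 without the technical duplicate, 55 in marker-built clusters and 0 in all endocrine clusters (edgeR, 4046 at an unadjusted p under 0.05). Without the pair as a block it gave 0 (111 unadjusted). Without pair 1 it gave 26, without pair 2 60 and without pair 3 11. Factors at 2 counts (4288) gave 2287 in DESeq2, 8301 without the filter, 516 with no block, 2327 to 3646 leaving out a unit, 2350 at 10% mitochondrial counts, 10157 at 5 counts, and with calls above the background 10543, or 48658 in all endocrine clusters. Single barcodes (36809) gave 22648 to 33699 leaving out a unit, 5740 in beta-like cells, where fewer barcodes could be fitted, and 17217 matched on UMIs. With other references they gave 31806 against cells with no call and 51656 against the BFP barcode (24915 higher, 26741 lower). Own transcripts were higher for 9 to 10 factors leaving out a unit.

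Any call (3104) gave 1 with no block, 1321 to 2944 leaving out a unit, 545 in beta-like cells and 2030 per donor. BFP (4414) gave 1613 to 3985 leaving out a unit, 1954 in beta-like cells and 2069 per donor. Of the gene lists, the 20 for FADplus became 0 with an estimated correlation and 0 by fry, the 12 for any call 0 and 4, and the 9 for BFP 0 and 4. Pool against control (610) gave 1904 at a fold of 1.5, 253 at 50 CPM, 360 with TMM, 189 in pool cells with no call, 1061 in score-named clusters, 674 in all endocrine clusters and 207 in these with no call on both sides.

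The share difference of beta-like cells was 42.16 in marker-built clusters. Barcode-positive shares of pool and control cells were 99.409 and 39.937 at 1 count, 88.393 and 11.132 at 5, 89.38 and 7.335 thinned, and 82.993 and 4.607 as calls above the background. Directions reversed for MT1A in all endocrine clusters (0.46), and in beta-like cells for SERPINH1 (-0.009) and HSPA6 (-0.44) with BACH2 and DDIT4 with any call (-0.313). For pool against control they reversed for islet COL1A1 (1.88) and G6PC2 (0.638) in pool cells with no call, islet MAFA in all endocrine clusters (0.63), and in all endocrine clusters with no call on both sides FADplus GCG (0.096) and TRIB3 (-0.226) and islet HSPA5 (-0.23).

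Not run were any barcode against none, the contrasts with barcode-negative cells and pool against control with such cells, since cells with 0 barcode counts were almost absent, and the single-barcode fit at 2 counts. BNC2 and EBF1 had too few units at 2 counts. In the BFP comparison edgeR recovered 14.7% and DESeq2 37.3% of simulated changes of 2-fold.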

Other observations

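The control FADplus comparison and the single-barcode, any call and BFP comparisons were chosen after the data were seen. In the control FADplus library, BFP cells had more HSPA1A (855.52 CPM against 82.17 in no-call cells) and HSPA6 (646.75 against 47.96), while INS was level (log2 ratio -0.03). Cholesterol synthesis genes were higher in 11 of 11 members (median 0.55) and unfolded protein response genes in 21 of 24 (median 0.42), against a median of all genes of 0.109.

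Other splits of the units were fitted for each count. For any call (3104) and for BFP (4414) the real split was 1 of 35 with as many genes, and the highest other gave 0 in edgeR. Only 8 of these splits part the arms of every unit, as the real one does, which is too few for a share under 0.05. For single barcodes the real split, 36804 calls over the barcodes when refitted (36809 in the report), was 1 of 40 with as many. The others were random regroupings of the barcodes within each unit, and the highest gave 2451. This argues against a random grouping of these sums. It does not cover variation between donors, since the units come from 2 donors. For factors at 2 counts the splits were fitted for 9 of the 13 factors. Of 35 splits 3 gave as many as the real 2898. The highest other, 5293, came from 2 splits that part the arms of 2 of the 4 units, so with the unit as a block they rest on the difference between the arms within those units. Among the 8 splits that part every unit the highest other gave 39, and these are too few for a share under 0.05. For FADplus against islet 3 of 10 splits gave as many as the real 11, which is too few splits for a share under 0.05. The highest other, 310, came from 2 splits that part 1 of the 3 pairs, so with the pair as a block they rest on the difference between the preparations within that pair. Among the 4 splits that part all pairs the highest other gave 6.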
